A study of Arabidopsis thaliana with 18 samples.

How the data were processed

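RNA sequencing was performed on whole Arabidopsis thaliana plants of the Col0 accession, grown in vitro on medium with 0.3 % sucrose at 20 °C with 16 h of light and no treatment, at Boyes stage 1.02, when 2 rosette leaves are visible. The labels give 6 genotypes, Col0, lst8-1, yak1, yak1lst8-1, maktor1g1 and maktor1g1maktor5g, and the titles number 3 libraries of each. The design text speaks of 2 biological replicates, so it is open whether 1 of the 3 libraries of a genotype repeats a plant pool. No 2 libraries of a genotype differed by as little as counting noise alone, since the chi-square per degree of freedom between them ranged from 2.99 to 22.8, where 1 is the value for counting noise. Separate libraries of 1 plant pool can also differ by more than counting noise, so this does not settle the question. All 3 libraries were used as replicates. If a pool was repeated, n = 3 counts libraries rather than pools, and the p-values may be too small. The series title also names tor, and none of the 18 libraries carries that name. The labels do not say which genes the maktor alleles affect.

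The authors selected polyadenylated RNA, made stranded single-end libraries and, per the labels, aligned reads to TAIR10 with TopHat2 and Bowtie2, whose versions are not stated. Per the file headers, reads with an equally good second alignment were removed, and the deposited values are counts of reads for 33602 gene models. The share of mapped reads removed for this reason was 1.85 to 2.22 %. All values were whole numbers. Whether the counting used the strand is not stated, so counts of genes that overlap on opposite strands are uncertain. The TAIR10.1 annotation served only for gene symbols, products and the order of genes along chromosomes. It held 32835 of the gene models and gave a symbol for 10654 of them; other genes are named by their identifier.

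Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr by genotype, which left 20619 genes. Library sizes were scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to all 18 libraries with the genotype as its term, which leaves 12 residual degrees of freedom. The common biological coefficient of variation was 10.8 %. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called at an adjusted p below 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and the quasi-likelihood F, and left out where F was below 0.01. Levels are TMM-scaled CPM, the count of a gene relative to the scaled library total, given as mean ± SD of 3 libraries. Limits that a count of 0 allows cover counting error only, since the deposited tables hold no molecular identifiers.

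The comparisons were each mutant against Col0, yak1lst8-1 against lst8-1 and against yak1, maktor1g1maktor5g against maktor1g1, and the interaction, which is the change from lst8-1 to yak1lst8-1 minus the change from Col0 to yak1. The effect of 1 genotype in both backgrounds was also compared across genes by covariance, correlation and a slope from which the error variance of the first comparison had been removed; these pairs of comparisons share no libraries, and their SE come from leaving out each library in turn.

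A set of 30 gene lists was fixed before the data were examined, as were the comparisons, tests and the rule for naming genes. The lists cover the TOR complex and YAK1, cytosolic ribosomal proteins, ribosome biogenesis, cell division, D-type cyclins, CDK inhibitors, sugar starvation and SnRK1 markers, starch synthesis, starch degradation, inositol and raffinose metabolism, nitrogen uptake, autophagy, abscisic acid and drought response, seed storage, nuclear-encoded photosynthesis genes, salicylic acid defence, jasmonate and ethylene defence, anthocyanin synthesis, glucosinolate metabolism, starvation for sulfur, phosphate and iron, expansins and xyloglucan enzymes, the circadian clock, heat shock, and markers of root hairs, root endodermis, other root tissues, the shoot meristem, and stomata and trichomes. Of 637 entries, 5 were dropped because their symbol belonged to another gene. Each list was tested against all other tested genes with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data; p-values were adjusted over the 30 lists. Beside the calls over all genes, members were also adjusted over the list alone.

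Genes were named by rule: the TOR complex and YAK1; the 5 largest rises and falls among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups; and up to 3 members with the smallest adjusted p of each list that passed or had at least 3 called members. The genes AT1G13390, AT1G76670, AT5G35935, AT5G37130 and AT3G01345 fall outside the rule and were chosen after their values were seen.

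The replicate numbers of the titles were checked as a possible pairing. The residuals of libraries with the same number correlated above 0.1 for all 3 numbers in 1 comparison, maktor1g1maktor5g against maktor1g1, at 0.428, 0.214 and 0.158. With the number as a block that comparison called 2 genes, as without it. Other comparisons changed more. Against Col0 the block moved the calls from 14 to 238 for maktor1g1 and from 14 to 653 for maktor1g1maktor5g. Libraries numbered 1 correlated at 0.244 to 0.554 between genotypes, and the main model has no block. Alternatives were other normalizations, other filters, DESeq2 1.42.0, the replicate number as a block, only the groups compared, organelle genes left out, stricter thresholds and leaving out each library in turn. For the overlap of calls against the shared Col0 libraries, the alternatives were added after seeing the data. The procedure was tested on simulated counts with the dispersions of the data and 200 changed genes. At a 2-fold change the test recovered 71.5 % of them for lst8-1 against Col0, 76.0 % for maktor1g1 against Col0, 74.5 % for yak1lst8-1 against yak1 and 59.5 % for the interaction; at 1.5-fold it recovered 50.0, 51.5, 45.0 and 8.00 %. Unchanged genes made up 3.85, 8.04, 14.3 and 0 % of the calls at 1.5-fold and 3.38, 1.94, 5.10 and 4.03 % at 2-fold. No library was left out.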

Results

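The data set held 18 libraries, 3 for each of 6 genotypes. LST8 is a subunit of the target of rapamycin (TOR) kinase complex, which promotes growth when nutrients are at hand, and YAK1 is a protein kinase. Total counts per library were 12872631 to 16499208 in Col0, 13099718 to 17281132 in lst8-1 and 12414300 to 15834555 in yak1. They were 10801464 to 17218178 in yak1lst8-1, 15381681 to 15654837 in maktor1g1 and 14134774 to 17548790 in maktor1g1maktor5g. A count of 0 in the shallowest library allows a level of up to 0.278 CPM, for counting error alone. Organelle transcripts were rare, as polyA selection leaves them: plastid genes took 0.0424 to 0.186 % of the counts.

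The first principal component held 32.3 % of the variance and the second 26.0 %. Libraries of lst8-1, yak1 and yak1lst8-1 stood apart from each other and from Col0, while both maktor genotypes lay near Col0. The third component, with 11.2 %, went with the replicate number: the 6 libraries numbered 1 scored −37.2 to −13.6 and the other 12 scored −7.52 to 28.4. Every genotype has 1 library of each number.

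**Figure D1:**
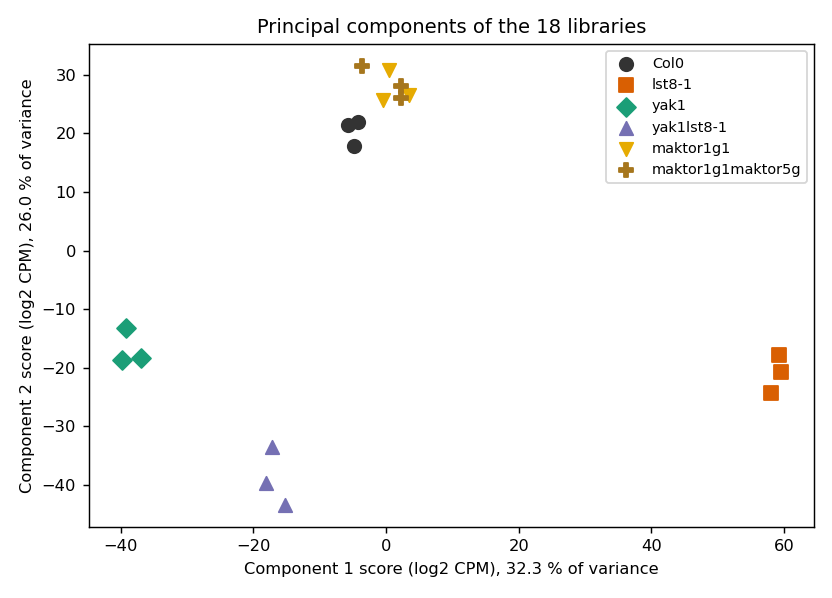
Scores of the 18 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, 1 point per library, with shape and colour for the genotype. The 3 lst8-1 libraries lie at 58.1 to 59.6 on component 1 and the 3 yak1 libraries at −39.9 to −36.9.

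Transcripts of the genes that the genotypes are named for were examined first. LST8-1 (AT3G18140, chromosome 3) stood at 50.7 ± 3.55 CPM in Col0 and at 2.31 ± 0.159 CPM in lst8-1 (SD, n = 3), a log2 fold change of −4.46 ± 0.12 (SE, adjusted p = 2.16e-14), and at 1.53 ± 0.554 CPM in yak1lst8-1. Every lst8-1 and yak1lst8-1 library had 13 to 39 counts of LST8-1, against 626 to 913 in the 12 others. LST8-2 (AT2G22040), its homolog, had a count of 0 in every library. YAK1 (AT5G35980, chromosome 5) was not lower but higher in the libraries labelled yak1, at 322 ± 75.6 CPM against 122 ± 20.3 CPM in Col0 (log2 fold change 1.39 ± 0.16, adjusted p = 6.11e-05). It was higher by the same measure in yak1lst8-1 than in lst8-1 (1.40 ± 0.16, adjusted p = 9.45e-06). The series design says that the genes were knocked out. Gene-level counts do not show whether these transcripts are intact, so what follows compares libraries by their labels. TOR itself, RAPTOR1 and LST8-1 were not called between yak1 and Col0, nor were these and YAK1 in either maktor genotype.

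**Figure D2:**
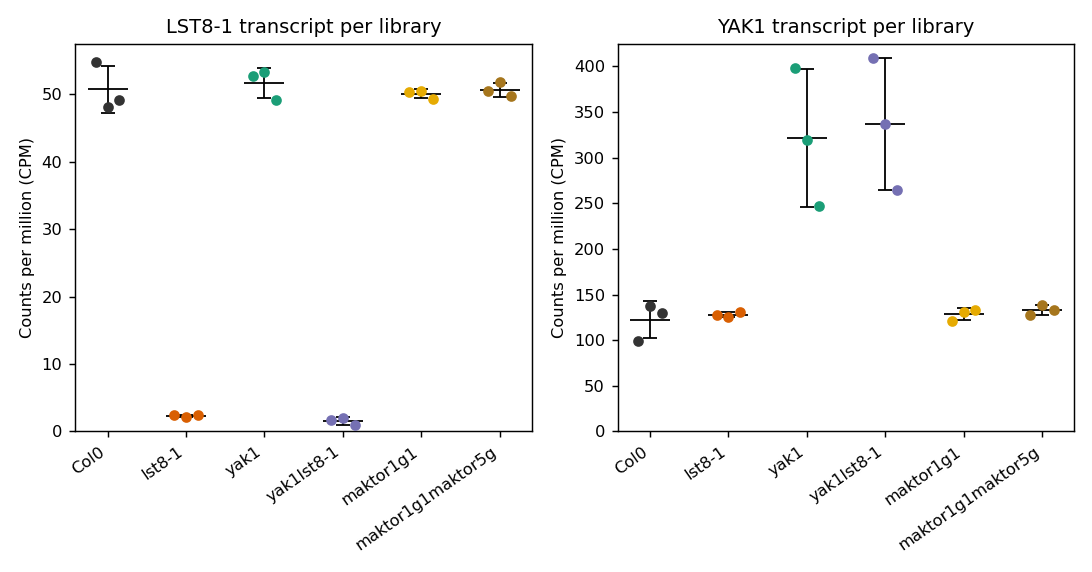
Level of LST8-1 (left) and YAK1 (right) in CPM in each library by genotype; points are libraries, and the line and bar are the mean and SD of 3. LST8-1 is at 1.53 to 2.31 CPM on average in lst8-1 and yak1lst8-1, and YAK1 is at 322 and 337 CPM on average in yak1 and yak1lst8-1 against 122 to 133 CPM in the 4 other genotypes.

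The comparison of lst8-1 with Col0 asked what loss of the LST8-1 transcript goes with. Root hair genes were called higher more often than lower and iron deficiency genes the other way, though neither list passed with an estimated correlation. RSL4, a transcription factor that drives root hair growth, was at 17.7 ± 4.18 CPM against 4.11 ± 0.391 CPM in Col0 (adjusted p = 2.80e-07). LRX1, a cell wall protein of root hairs, rose by 1.86 ± 0.31 on the log2 scale and SHV2 by 1.14 ± 0.16. Of the 11 root hair and root epidermis markers tested, 8 rose and none fell, with a median of 1.14 (adjusted p = 1.99e-05 by camera, adjusted p = 0.379 with an estimated correlation, over the list alone 8 higher and 1 lower). Lists of other root tissues did not pass: of 10 endodermis markers 2 rose and none fell (median 0.27, adjusted p = 0.166), and of 10 other root markers 4 rose and 1 fell (median 0.94, mean 0.44, adjusted p = 0.586). Of the 18 iron deficiency genes, 10 fell and none rose (median −0.95, adjusted p = 1.99e-05, adjusted p = 0.379 with an estimated correlation, 10 lower over the list alone). Among them the transcription factors of iron uptake bHLH38 and bHLH39 fell by 2.00 ± 0.23 and 1.34 ± 0.25.

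Of 27 glucosinolate genes, 14 fell and 1 rose in lst8-1 (median −0.44, adjusted p = 3.42e-05, adjusted p = 0.611 with an estimated correlation, 16 lower and 2 higher over the list alone). The myrosinase TGG2, which cleaves glucosinolates, fell by 3.36 ± 0.24 and CYP83A1, an enzyme of aliphatic glucosinolate synthesis, by 1.43 ± 0.15, whereas MYB34, a regulator of the indolic branch, rose by 0.96 ± 0.08. ESM1, which steers the products of glucosinolate breakdown, fell by 3.89 ± 0.18. Of 23 salicylic acid defence genes, 7 fell and 1 rose (median −1.11, adjusted p = 0.000337, adjusted p = 0.713 with an estimated correlation, 8 lower and 1 higher over the list alone). FMO1, needed for systemic acquired resistance, was at 0.0861 ± 0.0333 CPM in lst8-1 and 3.60 ± 1.22 CPM in Col0 (adjusted p = 9.96e-05). ALD1 was at 0.0724 ± 0.0786 and 1.14 ± 0.170 CPM (adjusted p = 0.000246), and the salicylic acid exporter EDS5 rose by 0.76 ± 0.16. The jasmonate-responsive CORI3 fell by 3.49 ± 0.31, while VSP1, also induced by jasmonate, rose by 2.73 ± 0.29; of 23 jasmonate and ethylene genes, 4 rose and 6 fell (adjusted p = 0.586).

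Ribosome biogenesis genes were called higher in lst8-1 in 11 of 25 cases and lower in none (median 0.36, adjusted p = 0.000230, adjusted p = 0.713 with an estimated correlation, 17 higher over the list alone). PRH75, a nucleolar RNA helicase, rose by 0.48 ± 0.10, SWA1 by 0.70 ± 0.16 and NAP57 by 0.71 ± 0.16. Of the 71 cytosolic ribosomal proteins, 1 rose and 1 fell (adjusted p = 0.586, 1 higher over the list alone). Of 36 cell division genes, 10 fell and none rose (median −0.41, adjusted p = 0.000621, adjusted p = 0.822 with an estimated correlation, 10 lower over the list alone). CYCB1;4 fell by 0.82 ± 0.16 and the replication factor CDC6 by 1.68 ± 0.32. Of 23 sugar starvation genes, 8 rose and 3 fell (median 0.08, adjusted p = 0.00470, adjusted p = 0.713 with an estimated correlation, 8 and 3 over the list alone). The proline dehydrogenase ERD5 rose by 2.76 ± 0.13, to 534 ± 30.4 CPM from 79.0 ± 8.45 CPM, and glutamate dehydrogenase GDH2 by 1.76 ± 0.17. Of 30 abscisic acid and drought genes, 14 rose and 4 fell (median 0.43, adjusted p = 0.000301, adjusted p = 0.713 with an estimated correlation, 14 and 4 over the list alone). The abscisic acid hydroxylase CYP707A1 rose by 2.14 ± 0.14 and the transcription factor ABF4 by 0.66 ± 0.08. Of 15 starch degradation genes, 9 fell, PHS2 by 0.80 ± 0.08, and 2 rose, BMY3 by 1.23 ± 0.14 (median −0.38, adjusted p = 0.00121, adjusted p = 0.611 with an estimated correlation, 9 and 2 over the list alone). Of 46 photosynthesis genes, 8 fell and 1 rose (median −0.15, adjusted p = 0.0223, adjusted p = 0.944 with an estimated correlation, 6 lower over the list alone). In the TOR complex, RAPTOR1 rose by 0.47 ± 0.09 and RAPTOR2 by 0.66 ± 0.12 beside the fall of LST8-1. The median of the 5 genes was 0.32 while their mean was −0.59 and camera put the list down (adjusted p = 0.00146, adjusted p = 0.379 with an estimated correlation, over the list alone 3 higher and 1 lower). This list holds LST8-1, so its result in any comparison of libraries with and without the label lst8-1 restates the low LST8-1 transcript.

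Of 15 clock genes 6 rose and none fell in lst8-1, but the list did not pass (median 0.17, adjusted p = 0.162, 6 higher over the list alone). CCA1 rose by 1.09 ± 0.23 and RVE8 by 0.92 ± 0.16.

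The largest rises in lst8-1 were in genes at low levels in Col0. SADHU3-1 was at 11.5 ± 4.69 CPM in lst8-1 and 0.145 ± 0.141 CPM in Col0, and the triterpene synthase gene AT5G36150 rose by 5.60 ± 0.32. The ethylene synthesis gene ACS9 rose by 4.68 ± 0.51 and the drought-inducible linker histone HIS1-3 by 4.42 ± 0.18, to 76.2 ± 5.76 CPM from 3.55 ± 0.765 CPM. Among the largest falls was that of COR413IM1, a cold-regulated chloroplast membrane protein, at −4.89 ± 0.26 (2.31 ± 0.730 CPM against 68.0 ± 11.4 CPM).

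Across all tested genes, edgeR called 5673 genes in lst8-1, 2902 higher and 2771 lower, and 1366 of them changed at least 2-fold. With an estimated correlation none of the 11 lists past the preset correlation passed. RLE size factors gave 2829 higher and 2837 lower, and DESeq2 2723 and 2774.

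Libraries labelled yak1 were compared with Col0 to see what goes with that genotype where LST8-1 is intact; the YAK1 transcript was higher in them, as given above. Salicylic acid defence genes rose: 16 of 23 were called higher and none lower, with a median of 2.13 (adjusted p = 3.10e-10, adjusted p = 0.769 with an estimated correlation, 17 higher and 1 lower over the list alone). ALD1 rose by 2.51 ± 0.32 (6.44 ± 2.90 CPM against 1.14 ± 0.170 CPM), FMO1 by 2.67 ± 0.35 and the transcription factor WRKY70 by 2.83 ± 0.48. The defence-related LURP1 and PCC1 rose by 4.49 ± 0.88 and 4.29 ± 0.76, with wide spread between the yak1 libraries (86.2 ± 70.1 CPM for LURP1). When only the yak1 and Col0 libraries were fitted, LURP1, PCC1, FMO1 and WRKY70 were no longer called, with adjusted p of 0.0850, 0.0683, 0.0592 and 0.0722.

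Iron deficiency genes were higher in the libraries labelled yak1 than in Col0: 7 of 18 rose and none fell (median 0.44, adjusted p = 0.000121, adjusted p = 0.769 with an estimated correlation, 11 higher and 1 lower over the list alone). BHLH101 rose by 1.75 ± 0.29, the ferric reductase FRO3 by 0.50 ± 0.10 and the transporter OPT3 by 0.53 ± 0.13. Of 46 photosynthesis genes 5 rose and none fell (median 0.15, adjusted p = 0.000275, adjusted p = 0.829 with an estimated correlation, 5 higher over the list alone). The Rubisco subunit gene RBCS2B rose by 0.77 ± 0.12. Starch degradation and autophagy genes were called lower more often than higher. Of 15 starch degradation genes 9 fell and 1 rose (median −0.34, adjusted p = 1.79e-05, adjusted p = 0.769 with an estimated correlation, 9 and 1 over the list alone). DPE1 was at −0.63 ± 0.10 and SEX4 at −0.57 ± 0.09. Of 29 autophagy genes 10 fell and 1 rose (median −0.27, adjusted p = 0.000121, adjusted p = 0.829 with an estimated correlation, 14 lower and 1 higher over the list alone). ATG8D and ATG8G, ubiquitin-like proteins of the autophagosome membrane, were at −0.72 ± 0.09 and −0.85 ± 0.16. No ribosome biogenesis gene of 25 was called, though the list passed camera (median −0.25, adjusted p = 0.00106, adjusted p = 0.829 with an estimated correlation, none over the list alone).

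Clock genes moved in opposite directions, and camera did not call the list (adjusted p = 0.330): of 15 tested, 4 rose and 8 fell, or 5 and 10 over the list alone, and the median was −0.39 while the mean was 0.12. The morning-phased LHY rose by 2.63 ± 0.17, to 54.3 ± 11.9 CPM from 8.77 ± 0.667 CPM, and RVE8 by 1.67 ± 0.16, while the evening-phased FKF1 fell by 0.95 ± 0.10. The labels give no harvest time. MRD1, a gene known to fall when methionine accumulates, rose by 5.82 ± 0.24 (adjusted p = 1.63e-11), and the ankyrin gene ANK by 4.83 ± 0.82. The 5 largest falls of genes with a symbol and at least 5 CPM in Col0 were in the cytochrome P450 gene CYP97B3 (−2.41 ± 0.11), the receptor kinase gene CRK31 (−1.98 ± 0.25), DR4 (−1.90 ± 0.20), the cold-regulated COR27 (−1.80 ± 0.29) and MLP328 (−1.55 ± 0.17).

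Altogether 2446 genes were called, 1186 higher and 1260 lower; of the 444 that changed at least 2-fold, 310 were higher and 134 lower. With library totals in place of TMM the split was 905 higher and 1541 lower, with RLE size factors 1279 and 1181 and by DESeq2 1392 and 1192. The number of calls was 929 when only the yak1 and Col0 libraries were fitted and 4111 with the replicate number as a block.

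The comparison of yak1lst8-1 with lst8-1 asked what the yak1 genotype goes with where LST8-1 is low. Iron deficiency genes rose in 17 of 18 cases and fell in none (median 1.87, adjusted p = 8.65e-17, adjusted p = 0.0345 with an estimated correlation, 17 over the list alone). BHLH101 rose by 3.11 ± 0.32, bHLH38 by 2.52 ± 0.22 and CYP82C4, an enzyme that makes an iron-mobilising coumarin, by 4.72 ± 0.53. Salicylic acid defence genes rose in 14 of 23 cases and fell in none (mean 2.48, adjusted p = 8.09e-07, adjusted p = 0.641 with an estimated correlation, 15 over the list alone). FMO1 was at 5.71 ± 0.375 CPM against 0.0861 ± 0.0333 CPM, and ALD1 at 2.41 ± 0.369 against 0.0724 ± 0.0786 CPM. PBS3, which acts in salicylic acid synthesis, rose by 4.74 ± 0.70. The wall-associated kinase WAK1 rose by 5.17 ± 1.00 and the ubiquitin ligase PUB54 was at 5.21 ± 3.58 CPM against 0.105 ± 0.0239 CPM.

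Ribosome biogenesis genes fell in yak1lst8-1 relative to lst8-1, 20 of 25 with none higher (median −0.64, adjusted p = 4.11e-10, adjusted p = 0.641 with an estimated correlation, 22 over the list alone). PRH75 fell by 0.82 ± 0.10, TOZ by 1.03 ± 0.15 and AT5G27120, which encodes a NOP56-like protein, by 1.22 ± 0.17. Photosynthesis genes rose in 27 of 46 cases and fell in 1 (median 0.34, adjusted p = 8.09e-07, adjusted p = 0.738 with an estimated correlation, 29 and 2 over the list alone). RBCS1A rose by 0.55 ± 0.10 and RBCS2B by 0.93 ± 0.12. Sugar starvation genes fell in 10 of 23 cases and rose in none (median −0.15, adjusted p = 0.000233, adjusted p = 0.641 with an estimated correlation, 10 over the list alone). ERD5 fell by 2.24 ± 0.13, DYL1 by 1.34 ± 0.16 and GDH2 by 1.25 ± 0.17. Glucosinolate genes rose in 12 of 27 cases and fell in 2 (median 0.27, adjusted p = 0.00146, adjusted p = 0.641 with an estimated correlation, 13 and 2 over the list alone). TGG2 rose by 2.85 ± 0.23 and MYB29, a regulator of the aliphatic branch, by 2.84 ± 0.31, while IMS2 fell by 1.31 ± 0.11. Of 14 sulfur starvation genes 7 rose and 1 fell (median 0.51, adjusted p = 0.0187, adjusted p = 0.641 with an estimated correlation, 8 and 1 over the list alone). Of 25 nitrogen genes 8 rose and 3 fell (median 0.25, adjusted p = 0.0276, adjusted p = 0.641 with an estimated correlation, 8 and 3 over the list alone). The chloroplast glutamine synthetase GS2, which is among the 100 tested genes nearest YAK1, rose by 0.68 ± 0.08. Autophagy genes fell in 15 of 29 cases and rose in 1 (median −0.27, adjusted p = 0.00277, adjusted p = 0.641 with an estimated correlation, 16 and 2 over the list alone), ATG3 by 0.45 ± 0.06.

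Of 15 clock genes 4 rose and 10 fell (median −0.57, adjusted p = 0.00221, adjusted p = 0.518 with an estimated correlation, 4 and 10 over the list alone). LHY rose by 3.32 ± 0.17 and PCL1 fell by 0.97 ± 0.08. Of 11 root hair markers 4 fell and none rose, RSL4 by 1.37 ± 0.18, but the list did not pass (adjusted p = 0.0546, 4 lower over the list alone). Some genes that had risen most in lst8-1 were lower in yak1lst8-1, and part of this is built in, since both comparisons use the lst8-1 libraries: SADHU3-1 was at 0.172 ± 0.185 CPM against 11.5 ± 4.69 CPM and HIS1-3 fell by 3.97 ± 0.17. AT5G36150 was at 8.51 ± 1.95 CPM against 53.0 ± 12.4 CPM (log2 fold change −2.65 ± 0.25). Of the 5 genes of the TOR complex list YAK1 rose, as given above, and 4 fell: RAPTOR1 by 0.53 ± 0.09, LST8-1 by 0.62 ± 0.19, TOR by 0.39 ± 0.13 and RAPTOR2 by 0.31 ± 0.11. The list did not pass (median −0.39, mean −0.09, adjusted p = 0.635, 1 higher and 4 lower over the list alone). LST8-1 was no longer called without lst8-1 replicate 1 (adjusted p = 0.0667), without yak1lst8-1 replicate 3 (0.265) or when only the groups compared were fitted (0.141). TOR was no longer called without lst8-1 replicate 1 (0.0716) or yak1lst8-1 replicate 2 (0.0644) or 3 (0.0638), and RAPTOR2 lost its call in 8 of the alternatives, DESeq2 among them (0.0663). In all 6804 genes were called, 3386 higher and 3418 lower; of the 1308 that changed at least 2-fold, 839 were higher and 469 lower. The balance depends on the scaling and the tool: library totals gave 2710 higher and 4050 lower, RLE size factors 3514 and 3317, and DESeq2 3394 and 3102.

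**Figure D3:**
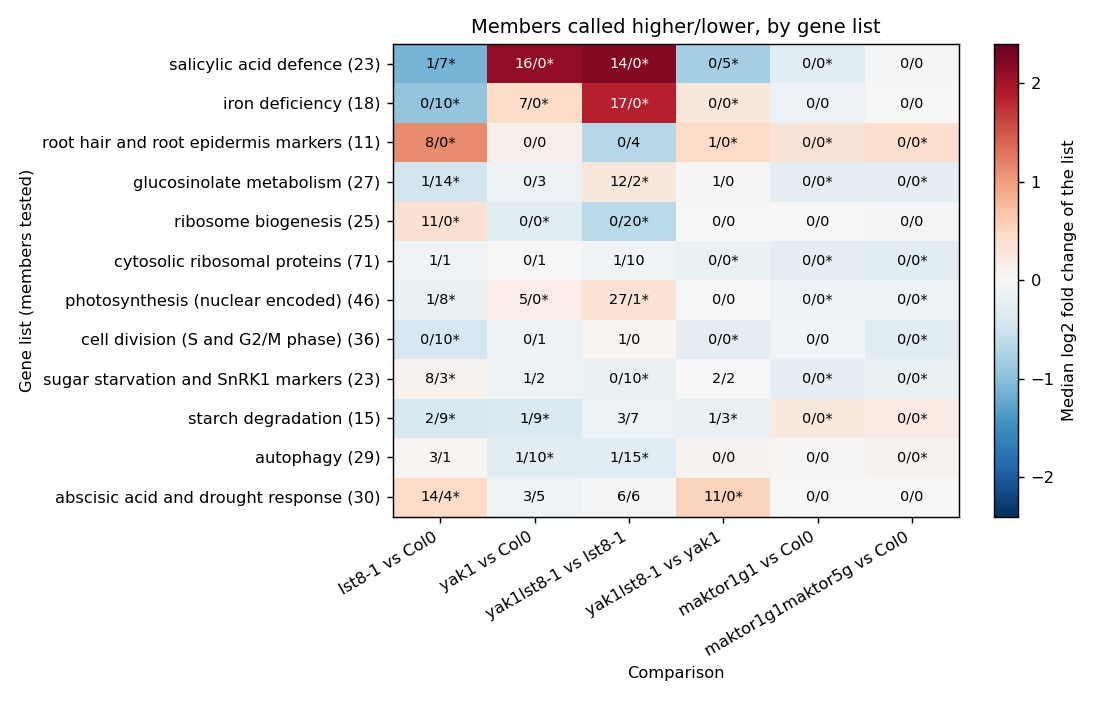
Median log2 fold change (colour) of 12 gene lists (y axis, with the number of members tested) in 6 comparisons (x axis); the text in each cell is the number of members called higher/lower, and a star marks an adjusted p below 0.05 by camera with the preset correlation. Iron deficiency genes fell in lst8-1 (10 of 18) and rose in yak1lst8-1 relative to lst8-1 (17 of 18), while no salicylic acid defence gene was called in either maktor genotype.

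Whether lst8-1 goes with a smaller change where the label also says yak1 was tested by comparing both effects. Between yak1lst8-1 and yak1, 616 genes were called, 387 higher and 229 lower, against the 5673 between lst8-1 and Col0. LST8-1 fell by 5.10 ± 0.13 in this comparison. AT5G36150 rose by 3.78 ± 0.41, VSP1 by 2.72 ± 0.32, DAA1 by 2.54 ± 0.26 and CYP97B3 by 2.22 ± 0.11, and MRD1 fell by 1.73 ± 0.16 and GSTF14 by 1.98 ± 0.30. Abscisic acid genes rose in 11 of 30 cases and fell in none (median 0.53, adjusted p = 1.50e-15, adjusted p = 0.120 with an estimated correlation, 15 over the list alone). CYP707A1 rose by 0.93 ± 0.14 and the dehydrin LTI30 by 0.79 ± 0.11. Sulfur starvation genes rose in 3 of 14 cases (median 0.30, adjusted p = 1.58e-09, adjusted p = 0.120 with an estimated correlation, 10 higher and 1 lower over the list alone). Salicylic acid genes fell in 5 of 23 (median −0.80, adjusted p = 1.42e-07, adjusted p = 0.593 with an estimated correlation, 8 lower and 1 higher over the list alone). No iron deficiency, ribosome biogenesis or photosynthesis gene was called here by edgeR, though the list passed for iron deficiency (median 0.28, adjusted p = 0.0375, adjusted p = 0.742 with an estimated correlation, none over the list alone). Root hair markers rose in 1 of 11 cases (median 0.47, adjusted p = 0.000200, adjusted p = 0.374 with an estimated correlation, 5 higher over the list alone). Starch degradation genes fell in 3 of 15 cases and rose in 1 (median −0.15, adjusted p = 0.00599, adjusted p = 0.593 with an estimated correlation, 7 and 2 over the list alone). Inositol and raffinose genes rose in 2 of 13 cases (median 0.20, adjusted p = 0.0334, adjusted p = 0.374 with an estimated correlation, 4 over the list alone), a list that did not pass with the replicate number as a block. None of 36 cell division genes (median −0.23, adjusted p = 0.00197, adjusted p = 0.792 with an estimated correlation) and none of 71 cytosolic ribosomal proteins (median −0.16, adjusted p = 2.56e-07, adjusted p = 0.792 with an estimated correlation) was called, and both lists passed. Over all genes 3156 had an unadjusted p under 0.05 and DESeq2 called 824. In the TOR complex list, which holds LST8-1, only that gene was called, and the median of 0.17 differed in sign from the mean of −0.86 and from the test (down, adjusted p = 1.50e-15, adjusted p = 0.000724 with an estimated correlation, 1 higher and 1 lower over the list alone). The count rests on single libraries: it was 358 without yak1 replicate 1, 306 without yak1 replicate 2 and 299 without yak1lst8-1 replicate 2, and 333 when only these 2 groups were fitted, against 1601 with the replicate number as a block.

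Of the 2902 genes called higher in lst8-1 than in Col0, 338 were also called higher in yak1lst8-1 than in yak1 (11.6 %), and the median log2 fold change of the 2902 was 0.59 in the first comparison and 0.20 in the second. Of the 2771 called lower, 182 were called lower in the second (6.57 %), with medians of −0.52 and −0.14. Across all 20619 genes both effects correlated (Pearson r = 0.553, Spearman rho = 0.454, genes are not independent replicates), with a noise-corrected slope of 0.355 ± 0.0521 (SE). The effect of the label yak1 was not smaller by the same measure: its slope between the Col0 and the lst8-1 backgrounds was 1.18 ± 0.139 (r = 0.614, rho = 0.543). Of the 1186 genes called higher and 1260 called lower in yak1 than in Col0, 816 and 866 were called the same way in yak1lst8-1 against lst8-1. Covariances of both pairs, which share no libraries, were 0.117 ± 0.0160 for lst8-1 and 0.179 ± 0.0134 for yak1.

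**Figure D4:**
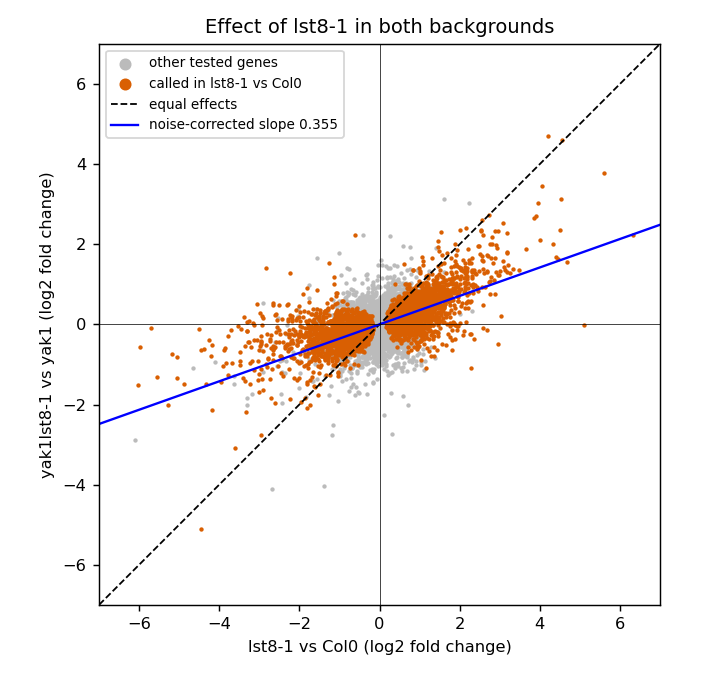
Log2 fold change of each tested gene in lst8-1 against Col0 (x axis) and in yak1lst8-1 against yak1 (y axis); orange points are the 5673 genes called in lst8-1 against Col0, the dashed line marks equal effects and the solid line the noise-corrected slope of 0.355. Called genes had medians of 0.59 and −0.52 on the x axis and 0.20 and −0.14 on the y axis; 4 genes lie outside the axes.

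The interaction tests the same question gene by gene. It was past the threshold for 714 genes, 435 positive and 279 negative. Of the 435 positive ones, 425 were called lower in lst8-1 than in Col0, and of the 279 negative ones 269 were called higher there; the interaction and that comparison share libraries, so the overlap is partly built in. The positive genes included COR413IM1 (3.40 ± 0.34, adjusted p = 7.59e-05), ESM1 (3.25 ± 0.23, adjusted p = 7.47e-07), MYB29 (2.98 ± 0.40, adjusted p = 0.000646), TGG2 (2.83 ± 0.31) and bHLH38 (2.47 ± 0.29). The negative ones included HIS1-3 (−2.73 ± 0.33), ERD5 (−1.99 ± 0.18) and RSL4 (−1.29 ± 0.27). Iron deficiency genes had a positive interaction in 8 of 18 cases (median 1.27, adjusted p = 7.55e-14, adjusted p = 0.0774 with an estimated correlation, 12 over the list alone). Salicylic acid defence genes had none of 23 called (median 0.32, adjusted p = 0.109). The count also rests on single libraries: it was 367 without Col0 replicate 2, 382 and 347 without lst8-1 replicates 1 and 2, 460 and 468 without yak1 replicates 1 and 2, and 350 and 381 without yak1lst8-1 replicates 2 and 3. It was 338 with only these 4 groups and 1889 with the replicate number as a block.

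Against Col0, yak1lst8-1 had 3903 called genes, 2119 higher and 1784 lower, 779 of them at least 2-fold; with library totals 1739 were higher and 2164 lower. Among the largest rises were MRD1 (4.09 ± 0.25), LHY (3.52 ± 0.17), the cold-induced KIN1 (3.31 ± 0.32) and the vegetative storage protein gene VSP2 (3.29 ± 0.38). Among the largest falls were LST8-1 (−5.08 ± 0.13), COR27 (−3.37 ± 0.35), RL5 (−2.76 ± 0.32) and GSTF14 (−2.25 ± 0.30). Salicylic acid defence genes went both ways and their list did not pass: PR5 was called lower, and PBS3 and WRKY70 higher. When only the groups compared were fitted they were at −2.17, 2.64 and 2.03 and were no longer called (adjusted p = 0.0592, 0.0624 and 0.0699 by edgeR). The starch synthase GBSS1 rose by 2.28 ± 0.17, but of 16 starch synthesis genes 4 rose and 4 fell (adjusted p = 0.762). Among starch degradation genes BMY3 rose by 1.69 ± 0.14, while PHS2 was at −0.94 ± 0.08 and DPE1 at −0.96 ± 0.10. Of 15 starch degradation genes 1 rose and 8 fell (median −0.44, adjusted p = 5.45e-08, adjusted p = 0.172 with an estimated correlation, 2 and 12 over the list alone). Of 18 iron deficiency genes 11 rose and none fell (median 0.56, adjusted p = 4.94e-06, adjusted p = 0.270 with an estimated correlation, 13 over the list alone). Of 30 abscisic acid genes 14 rose and 3 fell (median 0.43, adjusted p = 0.000297, adjusted p = 0.511 with an estimated correlation, 15 and 4 over the list alone). Cell division genes fell in 6 of 36 cases and rose in none (median −0.47, adjusted p = 0.000564, adjusted p = 0.781 with an estimated correlation, 6 over the list alone).

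In the same comparison 8 more lists passed with the preset correlation. Autophagy genes fell in 11 of 29 cases, ATG8D by 0.64 ± 0.09, and rose in 2 (median −0.20, adjusted p = 0.00983, adjusted p = 0.718 with an estimated correlation, 13 and 2 over the list alone). Of 46 photosynthesis genes 7 rose, RBCS2B by 0.89 ± 0.12, and none fell (median 0.14, adjusted p = 0.00427, adjusted p = 0.798 with an estimated correlation, 7 over the list alone). Root hair markers rose in 4 of 11 cases and fell in none (median 0.65, adjusted p = 0.0108, adjusted p = 0.511 with an estimated correlation, 6 over the list alone). Among 13 genes of inositol and raffinose metabolism 6 rose and 1 fell, with MIPS1 at 0.84 ± 0.24 and MIPS3 at −0.59 ± 0.12 (median 0.23, adjusted p = 0.0298, adjusted p = 0.463 with an estimated correlation, 6 and 1 over the list alone). Anthocyanin genes rose in 4 of 15 cases and fell in none, the reductase DFR by 2.28 ± 0.43 (median 0.48, adjusted p = 0.0382, adjusted p = 0.474 with an estimated correlation, 4 over the list alone); with the replicate number as a block this list did not pass. Ribosome biogenesis genes fell in 4 of 25 cases (median −0.26, adjusted p = 0.00427, adjusted p = 0.781 with an estimated correlation, 7 over the list alone) and cytosolic ribosomal proteins in 3 of 71 (median −0.15, adjusted p = 0.00427, adjusted p = 0.816 with an estimated correlation, 2 over the list alone), with none higher in either. In the TOR complex list YAK1 and RAPTOR2 were called higher and LST8-1 lower (median −0.06, mean −0.68, adjusted p = 7.19e-05, adjusted p = 0.0875 with an estimated correlation, 2 and 1 over the list alone), though RAPTOR2 lost its call in 8 of the alternatives.

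**Figure D5:**
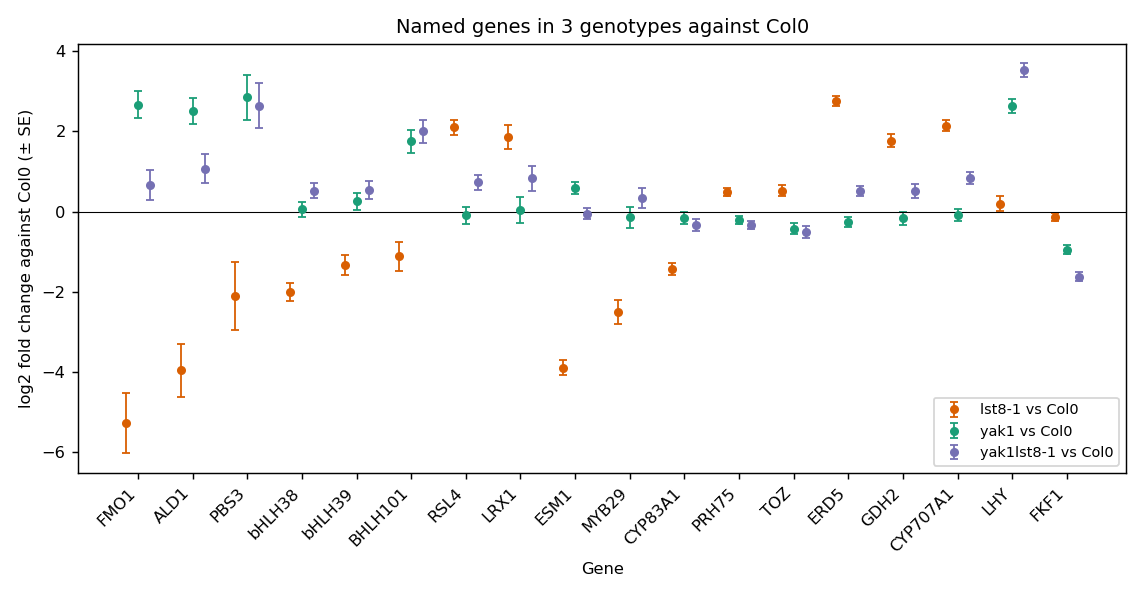
Log2 fold change against Col0 (y axis, point and SE bar) of 18 named genes (x axis) in lst8-1, yak1 and yak1lst8-1. ERD5 is at 2.76 in lst8-1, and LHY is at 2.63 in yak1 and 3.52 in yak1lst8-1.

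In maktor1g1, 14 genes were called against Col0, 7 in each direction, and in maktor1g1maktor5g also 14, 7 in each direction; 4 of the higher and 3 of the lower genes were shared. The clock gene ELF4 rose in both, by 0.71 ± 0.10 in maktor1g1 (65.5 ± 7.58 CPM against 39.9 ± 2.79 CPM, adjusted p = 0.00322) and by 0.75 ± 0.10 in maktor1g1maktor5g (adjusted p = 0.00167). PCL1, which acts with ELF4 in the evening complex of the clock, rose by 0.47 ± 0.07 and 0.53 ± 0.07. The median of 5 evening clock genes was 0.47 and 0.53 while that of LHY, CCA1 and RVE8, 3 morning genes, was −0.50 and −0.70, with none of these 3 called. FLC, a repressor of flowering, fell by 1.05 ± 0.14 and was at −0.96 ± 0.14 in maktor1g1maktor5g. The calls of ELF4 and FLC held in both genotypes under other normalizations, filters, fits and DESeq2 and without any single library, but a 2-fold minimum ends that of ELF4 in both and that of FLC in maktor1g1maktor5g. PCL1 was no longer called in maktor1g1 without maktor1g1 replicate 1 (adjusted p = 0.126) or 2 (0.0832), nor when only the groups compared were fitted (0.138, and 0.0944 in maktor1g1maktor5g). Of all called genes, AT1G13390 had the largest change in both genotypes. It was at −5.17 ± 0.20 in maktor1g1 (adjusted p = 1.12e-11) and −4.84 ± 0.19 in maktor1g1maktor5g (adjusted p = 1.67e-11). AT1G13390, AT1G76670 and AT5G35935 were among the called genes and were chosen after their values were seen.

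Of 15 clock genes, 3 were called higher in maktor1g1 and 2 in maktor1g1maktor5g (adjusted p = 0.000211 and 0.00218, adjusted p = 0.190 and 0.476 with an estimated correlation, over the list alone 6 higher and 4 lower, and 7 higher and 4 lower). In maktor1g1 the call of the clock gene FKF1 was lost without any 1 of the 6 libraries, at adjusted p of 0.0541 to 0.188 by edgeR. No gene for a cytosolic ribosomal protein was called by edgeR in either maktor genotype. The 71 genes lay below the others as a list, with a median of −0.23 in maktor1g1 (adjusted p = 3.82e-22) and −0.28 in maktor1g1maktor5g (adjusted p = 1.41e-26); with an estimated correlation the adjusted p was 0.464 and 0.476. Starch degradation genes had medians of 0.23 and 0.19 with none of 15 called over all genes (adjusted p = 2.55e-08 and 1.10e-05, adjusted p = 0.190 and 0.476 with an estimated correlation); over the list alone 8 rose and 1 fell in maktor1g1, and 6 rose in maktor1g1maktor5g. In all 12 lists passed in maktor1g1 and 14 in maktor1g1maktor5g with the preset correlation, and none with an estimated one. Photosynthesis genes lay lower, with medians of −0.12 and −0.15 (adjusted p = 6.25e-06 and 7.92e-09), and glucosinolate genes too, at −0.24 and −0.21 (adjusted p = 6.99e-06 and 1.06e-05). Root hair markers lay higher, at 0.31 and 0.41 (adjusted p = 0.00734 and 0.0103). Sugar starvation genes lay lower, at −0.20 and −0.15 (adjusted p = 9.81e-05 and 0.000285), as did sulfur starvation genes (adjusted p = 9.97e-07 and 0.000123, medians −0.25 and −0.20), jasmonate and ethylene genes (adjusted p = 0.0138 and 0.0229) and expansins (adjusted p = 0.0171 and 0.0150). Starch synthesis genes lay higher (adjusted p = 0.000231 and 0.0153). Salicylic acid genes passed as lower in maktor1g1 (adjusted p = 0.0175, not past the threshold with the replicate number as a block). In maktor1g1maktor5g cell division genes passed as lower and autophagy and TOR complex genes as higher (adjusted p = 2.22e-05, 0.00273 and 0.0373). Outside the clock, 1 gene of these lists, of sulfur starvation, was called over all genes, lower in maktor1g1. At an unadjusted p under 0.05 there were 1759 genes in maktor1g1 and 2353 in maktor1g1maktor5g; DESeq2 called 102 and 157, and with the replicate number as a block edgeR called 238 and 653. The counts were 6, 8 and 6 without maktor1g1 replicates 1, 2 and 3, 25 without Col0 replicate 1 and 8 without maktor1g1maktor5g replicate 3.

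Against maktor1g1, 2 genes were called in maktor1g1maktor5g, both outside the rule for naming: AT5G37130, which encodes a protein prenylyltransferase family member, rose by 0.77 ± 0.09 (adjusted p = 0.00244, 75.5 ± 2.49 CPM against 44.2 ± 1.87 CPM), and AT5G35935 fell by 0.83 ± 0.12 (adjusted p = 0.0251). Of the lists 5 passed with the preset correlation and none with an estimated one (adjusted p = 0.994 for each), and no member of any was called. Cell division genes lay lower (median −0.14, adjusted p = 0.000891), as did cytosolic ribosomal proteins (adjusted p = 0.0299, not past the threshold with library totals) and photosynthesis genes (adjusted p = 0.0388). Autophagy genes (median 0.08) and salicylic acid genes (median 0.24) lay higher, both at an adjusted p of 0.00246. The TOR complex list did not pass (adjusted p = 0.608). At an unadjusted p under 0.05 there were 360 genes, and DESeq2 called 3. The count was 0 without maktor1g1 replicate 3 and 1 without any other of the 6 libraries.

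Both maktor genotypes were set beside lst8-1, since all 3 are compared with the same 3 Col0 libraries. Of the 14 genes called in maktor1g1, 3 were higher and 3 lower in lst8-1 as well, and 2 went the opposite way. If calls were independent, 0.985 and 0.941 would be shared and 1.93 would go the opposite way. For maktor1g1maktor5g 2 were shared among the higher and 3 among the lower, and 4 went the opposite way, with the same values for independent calls. AT1G76670, called higher against Col0 in all 5 other genotypes, was among the shared higher genes of both maktor genotypes. The shared calls, 6 and 5 in all, were 22 and 47 by DESeq2 and 66 and 211 with the replicate number as a block, and 9 for maktor1g1maktor5g without Col0 replicate 1. The covariance of log2 fold changes with lst8-1 was 0.0391 for maktor1g1 and 0.0352 for maktor1g1maktor5g, of which 0.0249 and 0.0250 come from the shared Col0 libraries in simulated data without differences. With 3 control libraries no division leaves 2 in each part, so this was not repeated on separate controls, and part of the excess may come from the shared ones.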

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

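Of the tests given here, those on the error of the comparison, mixed plants, exchanged labels and the clock genes were chosen only after the result was seen.

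A test of the interaction, which asks whether the effect of yak1 differs between the Col0 and lst8-1 backgrounds, put 714 genes past the threshold. The largest positive differences on the log2 scale were COR413IM1 at 3.40, ESM1 at 3.25, CYP82C4 at 3.14, CYP79F1 at 3.13 and MYB29 at 2.98. Among genes named by rule, the largest negative ones were ACS9 at −3.12, HIS1-3 at −2.73 and ERD5 at −1.99. UNE11 at −1.91 and CYP82F1 at −1.74 came next. Without yak1 replicate 1 ACS9 was at −1.97. Among iron deficiency genes bHLH38 was at 2.47, FRU at 1.82 and bHLH39 at 1.62. TGG2 was at 2.83 and CYP83A1 at 1.26 among glucosinolate genes, and AT5G26220 at 1.54, APR1 at 0.72 and AT1G04770 at 0.72 among sulfur starvation genes. For growth and sugar genes the values were −0.62 for PRH75, −0.87 for SWA1, −1.08 for GDH2 and −1.64 for BCAT-2, and the clock gene FKF1 was at −0.55. RSL4 was at −1.29, AT5G39850 at −1.23, XTH24 at −1.35, EXPA5 at 1.33 and EXP3 at 0.99. CYP707A1 was at −1.21, KIN2 at 0.98 and ERD10 at 0.73. The calls of CYP82C4, ACS9, UNE11, FRU, PRH75, SWA1, GDH2, BCAT-2, FKF1 and ERD10 were each lost without at least 1 single library.

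Lists with an interaction past camera's threshold had medians of 1.27 for iron deficiency, 0.31 for glucosinolate metabolism (6 of 27 called, all positive; adjusted p = 1.43e-09; 0.208 with an estimated correlation), 0.61 for sulfur starvation, −0.33 for ribosome biogenesis, −0.19 for sugar starvation and SnRK1 markers, −0.31 for the circadian clock, −0.70 for root hair markers, 0.13 for photosynthesis and −0.0915 for cytosolic ribosomal proteins. With an estimated correlation none of these 9 lists passed.

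Other splits of the same libraries were counted. For the interaction, 7 of 100 splits of the 12 libraries, the real one included, gave at least 714 genes, the highest other split gave 2378 and 82 gave none, so chance was not excluded by this count. These splits regroup libraries of genotypes that differed in up to 6804 genes, so their counts do not measure chance alone and leave the question open. The split with the highest count may carry these genotype differences, and which of them it carries was not tested. On simulated counts without effects of either genotype alone, the interaction called 0 to 7 unchanged genes. For pairwise comparisons the 10 splits of 6 libraries, of which 1 gave as many calls in each, are too few for a share under 0.05. The real counts were 5673 for lst8-1, 2446 for yak1, 3903 for yak1lst8-1, 14 for each maktor genotype, all against Col0, 6804 for yak1lst8-1 against lst8-1 and 2 for maktor1g1maktor5g against maktor1g1, and the highest other split gave 0 in each of these. For yak1lst8-1 against yak1 the real count was 616 and the highest other 250. The other splits mix both genotypes within a group, which can raise the spread within groups. Their low counts are therefore no support for the real ones.

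The effect of lst8-1 was smaller in the libraries labelled yak1, with a slope of 0.355. The ratio of the median standard errors was 1.02. All genotypes share 1 estimate of the spread per gene in the fit, so this ratio cannot show a larger error there. Leaving out 1 library at a time gave slopes of 0.313 to 0.385. With library totals only the slope was 0.357. Other scaling moves all genes of a comparison by nearly the same amount, which a slope ignores, so this cannot decide on the normalization factors. Plants with intact LST8-1 mixed into yak1lst8-1 are argued against by a highest LST8-1 level of 3.91 % of the yak1 mean. No biological explanation was tested, so the cause stays open.

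The YAK1 transcript was higher in the libraries labelled yak1. The adjacent tested genes AT5G35970 and AT5G35995 were not called in yak1 against Col0, and the larger change of the pair was 0.45 (adjusted p = 0.194). This argues against reads shared with a neighbour that itself rose. It cannot decide on read-through from a neighbour whose own level was unchanged. Genes removed by the filter on low counts were not covered. Labels exchanged with Col0 are argued against by the lowest of the 6 yak1 and yak1lst8-1 libraries, which had 1.78 times the YAK1 level of the highest of the 12 others. An insertion that leaves or drives part of the transcript may explain it and stays open, since counts per gene do not show where reads fall.

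Clock genes differed in the libraries labelled yak1. The median of 3 morning genes (LHY, CCA1 and RVE8) minus that of 5 evening genes (TOC1, GI, ELF4, PCL1 and FKF1) was 2.29 on the log2 scale in yak1 against Col0, with 1.71 for morning and −0.58 for evening genes, which is what a different time of day at harvest predicts. The lowest LHY level of the 6 libraries was 5.14 times that of the highest Col0 library, which argues against a single library deciding the rise of LHY. LHY had the largest change of these genes, and the others were not tested this way. In lst8-1 the medians were 0.92 and −0.11, with CCA1 and RVE8 called higher and LHY not called, while the evening gene GI was also called higher, by 0.23. Both maktor genotypes differed the opposite way, with medians of −0.50 and −0.70 for the morning and 0.47 and 0.53 for the evening genes. Harvest time and an effect of the genotype on the clock both stay open for all of these, and either may contribute. In each genotype against Col0, the median of the starch degradation genes had the opposite sign to that of the morning genes. Whether harvest time contributes to the changes of starch degradation genes was not tested.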

How the results depend on the processing

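Alternatives for the overlaps with shared Col0 libraries were chosen after seeing the data; all others were planned.

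No named gene and no list result was reversed in direction, but the majority of calls turned between higher and lower with RLE size factors and DESeq2 for lst8-1 and yak1 against Col0 and for yak1lst8-1 against lst8-1, and with library totals for yak1lst8-1 against Col0. It also turned with a 2-fold minimum for yak1 against Col0 and for yak1lst8-1 against lst8-1, for the latter with an adjusted p below 0.01 and with only the groups compared, and without 1 library (Col0 replicate 3 for lst8-1, yak1 replicate 1 for yak1, and 4 of 6 libraries for yak1lst8-1 against lst8-1). With a 2-fold minimum the counts of called genes were 1366 for lst8-1, 444 for yak1, 779 for yak1lst8-1, 5 for maktor1g1 and 5 for maktor1g1maktor5g against Col0, 1308 for yak1lst8-1 against lst8-1, 168 against yak1, 0 for maktor1g1maktor5g against maktor1g1 (edgeR; 360 genes at an unadjusted p under 0.05, 3 by DESeq2) and 314 for the interaction. At an adjusted p below 0.01 they were, in the same order, 3265, 1023, 2058, 5, 8, 4064, 249, 1 and 168. Both are fewer by construction.

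When only the groups compared were fitted, the counts were 929 for yak1, 5 for maktor1g1maktor5g, 333 for yak1lst8-1 against yak1, 1 for maktor1g1maktor5g against maktor1g1 and 338 for the interaction. With the replicate number as a block they were 4111 for yak1, 238 for maktor1g1, 653 for maktor1g1maktor5g, 1601 for yak1lst8-1 against yak1 and 1889 for the interaction. As a hint from the data, not the design, 14 of 18 libraries correlated best with libraries of their own number, those of number 1 at 0.244 to 0.554 between genotypes. DESeq2 called 102 for maktor1g1 and 157 for maktor1g1maktor5g. Library totals gave 32 for maktor1g1maktor5g against Col0 and 1 against maktor1g1, and no filter gave 23 for the former. The covariance of yak1 effects was 0.163 with a filter of at least 1 CPM in 3 libraries. Overlaps of calls with lst8-1 were 22 and 47 for maktor1g1 and maktor1g1maktor5g by DESeq2, and 66 and 211 with the block. Apart from the fewer libraries in a fit, the cause was not tested.

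Leaving out 1 library at a time gave 4134 to 5000 genes for lst8-1, 1665 to 2262 for yak1, 2853 to 3381 for yak1lst8-1, 6 to 17 for maktor1g1 and 8 to 25 for maktor1g1maktor5g against Col0. It gave 5150 to 6368 for yak1lst8-1 against lst8-1, 299 to 754 against yak1, 0 to 1 for maktor1g1maktor5g against maktor1g1 and 347 to 839 for the interaction. The covariance was 0.109 to 0.127 for lst8-1 and 0.165 to 0.185 for yak1, the slope 0.313 to 0.385 and 1.07 to 1.23, and the overlaps 5 to 6 and 4 to 9.

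Of 399 values of named genes, 2303 of 2585 recomputed without 1 library kept their call and 282 lost it; under other alternatives 3100 of 3183 kept it and 83 lost it. Of 89 list results past the threshold, 2 kept it with an estimated correlation (iron deficiency in yak1lst8-1 against lst8-1, and in yak1lst8-1 against yak1 the TOR complex list, which holds LST8-1 itself), 89 with RLE size factors, 87 with library totals and 86 with the block. At a 2-fold change the test on simulated data recovered 59.5 % of genes for the interaction and 71.5 % for lst8-1, so absent calls at this depth do not show absent changes.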

Other observations

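Tests on AT1G76670 and AT1G13390 were chosen after the result was seen; those on genes near YAK1 and LST8-1 were planned.

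AT1G76670, which encodes a nucleotide-sugar transporter family protein, was the 1 gene called higher against Col0 in all 5 other genotypes, and 0 genes were called lower in all 5 by edgeR. It was at 24.1 ± 0.906 CPM in Col0 and 81.8 ± 1.68 to 102 ± 2.11 CPM in the others (SD, n = 3). Its log2 fold changes differed by at most 0.32 between the 5 genotypes, which a difference carried by the Col0 libraries predicts. This may be a property of the Col0 plants used. AT1G76670 was also called in the interaction, at −1.81 ± 0.12 (adjusted p = 9.88e-08). A low level in Col0 alone gives both a rise in lst8-1 and a negative interaction.

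AT1G13390, annotated as a translocase subunit, was at 0.572 ± 0.283 CPM in maktor1g1 and 0.712 ± 0.149 CPM in maktor1g1maktor5g against 20.8 ± 1.52 CPM in Col0. It was at 33.6 ± 3.85 CPM in lst8-1, 11.9 ± 0.999 CPM in yak1 and 14.2 ± 0.654 CPM in yak1lst8-1. Whether a maktor allele affects this gene was not tested. A loss of a chromosome 5 gene in the genotype named for maktor5g was looked for, and 0 tested chromosome 5 genes were at least 4-fold lower in maktor1g1maktor5g than in maktor1g1. The labels do not say that maktor5g lies on chromosome 5, and genes removed by the filter on low counts were not covered. A mutated gene can also keep its transcript, as YAK1 did in the libraries labelled yak1, so this count cannot decide the question. AT5G35935, an uncharacterized gene near YAK1, was at 10.5 ± 0.653 CPM in Col0, 18.4 ± 1.48 CPM in lst8-1, 10.2 ± 1.09 CPM in maktor1g1maktor5g and 1.74 ± 0.328 CPM in yak1lst8-1. On the log2 scale against Col0 it was at −3.23 ± 0.18 in yak1 and 0.79 ± 0.12 in maktor1g1. AT3G01345 was at 0.558 ± 0.236 CPM in Col0, 218 ± 9.99 CPM in yak1 and 110 ± 3.96 CPM in yak1lst8-1.

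A chromosome segment from another background was tested on the 100 tested genes nearest YAK1 and LST8-1. Near YAK1 16 were called in yak1, 1.35 times the share among all genes (Fisher's exact test, two-sided, p = 0.213). Near LST8-1 21 were called in lst8-1, 0.763 times that share (Fisher's exact test, p = 0.177). Both tests count calls of any size. Near YAK1, AT5G35935 was at −3.23, AT5G35525 at −2.08, AT5G35480 at 1.71 and AT5G35940 at 1.56 in yak1 on the log2 scale. Each was called the same way in yak1lst8-1 against lst8-1, so a segment near YAK1 is not excluded.

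Among the lists that did not pass in lst8-1 against Col0, D-type cyclins had 1 higher and 1 lower of 9 (adjusted p = 0.797), CDK inhibitors 0 of 18 (0.914), starch synthesis 1 higher and 3 lower of 16 (0.586), inositol and raffinose metabolism 5 and 2 of 13 (0.232), seed storage 0 of 5 (0.632) and anthocyanin synthesis 6 and 4 of 15 (0.570). Phosphate starvation had 6 higher and 3 lower of 13 (0.166), expansins and xyloglucan enzymes 6 and 9 of 20 (0.971), heat shock 1 and 1 of 8 (0.990), nitrogen uptake 4 and 8 of 25 (0.162), autophagy 3 and 1 of 29 (0.570), sulfur starvation 4 and 4 of 14 (0.570), shoot meristem 0 of 7 (0.990), and stomata and trichomes 1 and 0 of 10 (0.914). In this comparison 8040 genes had an unadjusted p under 0.05, and DESeq2 called 5497.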
